A study of Platynereis dumerilii with 97 samples.

How the data were processed

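The series holds 97 single-embryo CEL-Seq libraries of Platynereis dumerilii. Per the labels' protocols, fertilized eggs from several matings were kept at 18 °C, an embryo was frozen every hour, and RNA was extracted with Trizol and amplified by CEL-Seq. The deposited table holds whole-number counts per transcript, not normalized, with 1 column per embryo; per the submitters' processing notes CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 were used, in roles and with settings not given in the sources used here. CEL-Seq as described there names no molecular identifiers, so counts are reads and can hold amplification copies. All 97 columns were matched to a sample, and no pair of embryos had identical counts.

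Besides 10908 transcripts the table lists 92 ERCC spike-ins, synthetic RNAs added to each sample, and 5 summary rows, which stayed out of library sizes and tests. Summary rows held 57.7% of all counts: 54.9% were reads not aligned and 2.75% reads aligned to no feature, and 3 rows were 0 throughout. Spike-ins held 4.09%. Transcript totals ran from 3555 to 2577933, with a median of 743666. At such totals a transcript of a few CPM has a handful of counts or fewer per embryo, so intervals and floors cover counting error only.

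Windows of hours, tests, the rule for named transcripts and most alternatives were set before the data were examined. Windows were compared with the edgeR 4.0.16 quasi-likelihood test (robust, TMM scaling, filterByExpr, R 4.3.3) on the embryos of both windows, with Benjamini-Hochberg adjusted p under 0.05 and log2 changes later over earlier. The standard error was taken as the absolute log2 change over the square root of F. The time course was tested with a natural spline of the hour with 5 degrees of freedom. In each comparison the 2 transcripts with the largest rise and the 2 with the largest fall were named, among those past the threshold with a mean of at least 50 CPM in the higher window. Where a window had 0 counts the fold was bounded as the pooled level of the other window, its summed counts over its summed scaled totals, over a floor of 3 counts in the window at 0, and with 1 to 3 counts a ratio with an exact 95% interval was given. Lists of genes by function were not tested, because the files do not pair identifiers with gene names.

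Principal components used log2 CPM (prior count 2) of the 2000 most variable transcripts. The best hour of an embryo was that of the Gaussian-smoothed profile of the others (bandwidth 3 h) with the highest Pearson correlation. The fastest change was sought as the distance between 5 embryos before and 5 after each border, less that of random splits of the same embryos, with 100 bootstrap draws. Detection at equal depth was the expected number of transcripts after thinning to the 10th percentile of totals. Single values were compared with two-sided permutation tests, exact where the number of splits allowed it and otherwise with 100000 resamples (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; plots with matplotlib 3.10.9).

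Each test across transcripts was checked on simulated counts with 200 changed transcripts. With a 4-fold change, 68% were recovered for 7 to 12 h against 1 to 6 h, 66% for 13 to 23 h against 7 to 12 h, 72% for 24 to 47 h against 13 to 23 h and 70% for 48 to 65 h against 24 to 47 h. Recovery was 28% for 66 to 120 h against 48 to 65 h, 10% for 66 to 120 h against 1 to 6 h and 16% for a gradual 4-fold change over the time course. With 64-fold changes the last 3 values were 54%, 20% and 78%. Between 1 and 7 unchanged transcripts were called per window comparison, and 46 of 8904 in the time course, so in that simulation false calls were a large part of the calls. In 9 simulated courses with swapped embryos, the first criterion, placement within 6 h of the true hour, was met by 49 of 54 swapped embryos and so was missed. All 54 lay within 12 h, with a largest error of 9.0 h; 12 h was taken as the bound for calling a library out of order after that result. The simulated jump was found at its hour in all 9.

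Alternatives set beforehand were DESeq2 1.42.0 size factors and tests, no filter on low counts, 1 fit over all windows, the library total as a covariate, the 10 embryos with the lowest totals left out, hours beside a border left out, and each embryo of the 6-embryo windows left out. For the time course they also held a stricter filter, splines with 3 or 8 degrees of freedom or of the log2 hour, and a fit without the embryo labelled 120 h. For order, best hour, border and detection they held other gene sets, prior counts, bandwidths, flank sizes, depths and Spearman correlation. Added after the data were seen were total-count and spike-in scaling, fits by library series, detection with PT_v1_tr_02502 left out, fits without the libraries labelled 21, 24, 48, 62 and 72 h, and fits without single libraries that held much of a named transcript's mean. These 5 were picked on a first look at depth, detection and similarity; no library was moved, and in the main results these 5 were left out only where their totals were below the depth used for detection, as for those labelled 21 and 62 h. The libraries labelled 95, 97 and 120 h, also more than 12 h from their best hour, were not among them. For the library labelled 120 h this distance was fixed in advance, as the latest hour on offer was 97 h. The check of spike-in spread was first run without equal depth and was repeated on spike-ins thinned to 48975 counts, since shallow spike-ins vary more by counting alone. The best hour of the library labelled 21 h without PT_v1_tr_02502 only repeats the match with it, because that transcript was not among the 2000 most variable, so it was not used to decide.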

Results

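The data set followed the marine annelid Platynereis dumerilii from the first hour after fertilization to the fifth day, with a single whole embryo per library. CEL-Seq, a method that tags the 3' ends of polyadenylated RNA and amplifies it by in vitro transcription, was applied to 97 embryos. Labelled ages ran hourly from 1 to 95 h, followed by 97 and 120 h. For comparison the embryos were placed in 6 windows by labelled hour: 1 to 6 h (n = 6), 7 to 12 h (n = 6), 13 to 23 h (n = 11), 24 to 47 h (n = 24), 48 to 65 h (n = 18) and 66 to 120 h (n = 32). These borders follow the usual staging of the species, in which cleavage gives way to a gastrula, then to swimming trochophore larvae and finally to segmented larvae. No 2 embryos shared an hour, so the spread within a window held development within it as well as differences between embryos, and nothing in the labels says which embryos shared parents.

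Transcript counts per embryo had a median of 743666 and reached 2577933. The library labelled 62 h held 3555 counts, and the next lowest total was 247000. The table listed 10908 transcripts by identifier, and the files do not pair these identifiers with gene names, so transcripts are given here by identifier alone. Embryos numbered 51 to 97 in the labels, which are those labelled 52 h and later together with the library labelled 24 h, differed from embryos 1 to 50 in library make-up. Transcripts with 1 to 5 counts formed 28.2% ± 7.70 (SD, n = 50) of the detected transcripts in embryos 1 to 50 and 6.49% ± 2.94 (SD, n = 47) in embryos 51 to 97. These sets are called the first and the second library series below. The labels name no batch, and the change between the series falls inside the window of 48 to 65 h.

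Transcript levels varied with age over the whole course, though how many did depended on whether the library series was in the fit. Of 9454 transcripts tested over all 97 embryos, 6353 varied with the hour (edgeR quasi-likelihood test of a spline, Benjamini-Hochberg adjusted p under 0.05). Transcripts that varied were spread over the whole course: 1161 had their highest mean level at 1 to 6 h, 948 at 7 to 12 h, 940 at 13 to 23 h, 1458 at 24 to 47 h, 628 at 48 to 65 h and 1218 at 66 to 120 h (743 by the median in place of the mean). Transcripts highest at 66 to 120 h took 1.27% of transcript counts at 1 to 6 h and 20.8% at 66 to 120 h. Those highest at 1 to 6 h took 10.1% of counts in that window and 4.06% at 66 to 120 h. Each class was picked for its highest mean level in these same embryos. The direction of these changes in share can therefore follow from the choice itself, and part of their size may too. Embryos of 1 to 6 h are all in the first series and those of 66 to 120 h all in the second. These shares therefore do not separate age from library series. With the library series as a covariate 4032 transcripts varied with the hour, and within the first series alone 5500 of 8416 did. Within the second series alone 2339 of 10276 did, and 1524 of these were among the 6353.

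**Figure D1:**
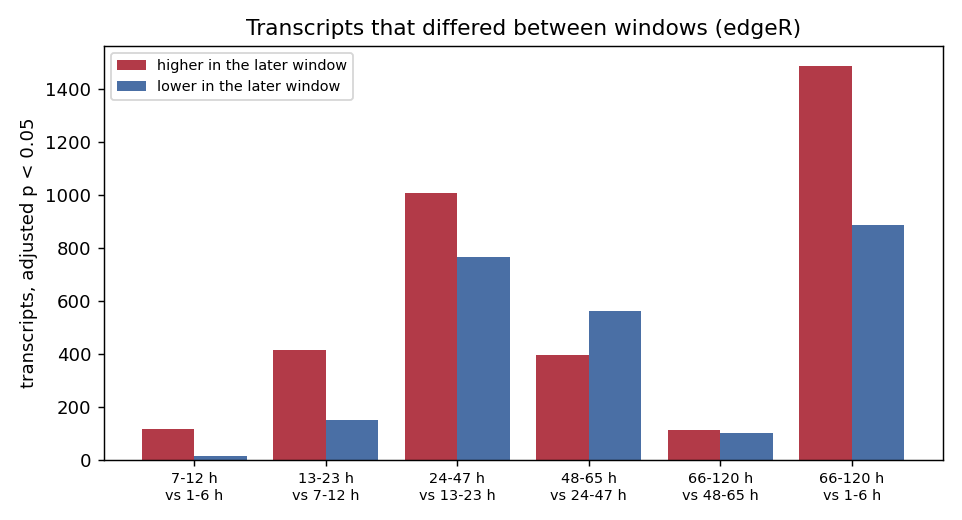
Number of transcripts with an adjusted p under 0.05 (y axis) in each comparison of 2 windows (x axis), in the edgeR test, with red bars for transcripts higher and blue bars for transcripts lower in the later window. Adjacent windows differed in between 131 and 1775 transcripts, and the first and last windows in 2375.

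The first comparison asked what changed between 1 to 6 h and 7 to 12 h. Almost all of the difference was a gain: 117 transcripts rose and 14 fell, of 3689 tested. PT_v1_tr_06540 went from 1 count in 6 embryos to 521 counts in 6 embryos, a level of 124 ± 74.2 CPM (SD, n = 6) and a ratio of 411 with an exact 95% counting interval of 73.5 to 16280 (log2 change 8.19, SE 0.77, adjusted p = 8.948e-06, edgeR). PT_v1_tr_10466 reached 124 ± 97.1 CPM (SD, n = 6) from 3 counts, a ratio of 120.5 with an exact 95% counting interval of 41.0 to 587 (log2 change 7.05, SE 0.86, adjusted p = 0.0001371, edgeR). The falls were smaller. PT_v1_tr_00768 fell from 846 ± 176 to 289 ± 152 CPM (SD, n = 6 each; log2 change -1.54, SE 0.29, adjusted p = 0.004582, edgeR). PT_v1_tr_07311 fell from 95.1 ± 41.4 to 27.5 ± 17.0 CPM (SD, n = 6 each; log2 change -1.84, SE 0.43, adjusted p = 0.02052, edgeR). The count of differing transcripts rested in part on single embryos: it was 216 without the library labelled 7 h, 79 without that labelled 10 h and 71 without that labelled 12 h. The call of PT_v1_tr_07311 ended without the library labelled 3 h (adjusted p = 0.05849, edgeR) or 12 h (adjusted p = 0.0549, edgeR), and that of PT_v1_tr_00768 with spike-in scaling (log2 change -1.30, adjusted p = 0.05995, edgeR). In a fit of all windows both falls kept their size and lost their call (log2 change -1.46, adjusted p = 0.8986 for PT_v1_tr_00768, and -1.84, adjusted p = 1.0 for PT_v1_tr_07311, edgeR).

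Between 7 to 12 h and 13 to 23 h, 413 transcripts rose and 149 fell, of 4514 tested. A fit of all windows gave 118 rises and 8 falls. PT_v1_tr_04580 had no count in the 6 earlier embryos and 79.8 ± 110 CPM (SD, n = 11) later, at least 120-fold above a floor of 3 counts over the earlier window (adjusted p = 0.004023, edgeR). Its later mean was 49.9 CPM without the library labelled 20 h, and the call stayed (adjusted p = 0.00247, edgeR). PT_v1_tr_03245 likewise went from 0 counts to 86.5 ± 157 CPM (SD, n = 11; at least 68.2-fold; adjusted p = 0.04705, edgeR), but 4 of the 11 later embryos had none, and the mean was 43.2 CPM without the library labelled 21 h. In fits without the libraries labelled 21, 24, 48, 62 and 72 h, the lowest totals or the library labelled 20 h it did not reach the test. Its call ended whenever any embryo of 7 to 12 h was left out, and with DESeq2 size factors (adjusted p = 0.06213), no filter (0.094), the library total as a covariate (0.09771) or border hours left out (0.05846, all edgeR). PT_v1_tr_05383 fell from 179 ± 67.1 (SD, n = 6) to 23.1 ± 25.0 CPM (SD, n = 11; log2 change -2.93, SE 0.56, adjusted p = 0.00255, edgeR). PT_v1_tr_10881 fell from 73.4 ± 49.7 (SD, n = 6) to 7.79 ± 14.4 CPM (SD, n = 11; log2 change -3.13, SE 0.85, adjusted p = 0.01915, edgeR), or 4.38 CPM without the library labelled 14 h. That call ended without the library labelled 9 h (adjusted p = 0.06338, edgeR) and with the library total as a covariate (adjusted p = 0.0568, edgeR), and both falls lost theirs in a fit of all windows (adjusted p = 0.1363 and 0.1531, edgeR). Scaling to the spike-ins left 124 rises and 146 falls, and total-count scaling 404 rises and 53 falls. Leaving out the library labelled 7, 8 or 9 h lowered the count of 562 to 371, 348 and 353.

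Between 13 to 23 h and 24 to 47 h, 1008 transcripts rose and 767 fell, of 5677 tested. This was the highest count among adjacent windows, which differ in size. With the library total as a covariate it was 1091, against 1122 for 48 to 65 h against 24 to 47 h. PT_v1_tr_06335 rose from 0 counts in 11 embryos to 50.5 ± 48.5 CPM (SD, n = 24; pooled level 55.3 CPM, at least 100.3-fold; adjusted p = 1.97e-05, edgeR) and PT_v1_tr_03027 from 0 counts to 55.6 ± 80.5 CPM (SD, n = 24; pooled level 63.9 CPM, at least 116-fold; adjusted p = 0.002123, edgeR). PT_v1_tr_03800 fell from 322 ± 215 (SD, n = 11) to 3.95 ± 7.23 CPM (SD, n = 24; log2 change -6.52, SE 0.58, adjusted p = 5.813e-10, edgeR). PT_v1_tr_08470 fell from 965 ± 1668 (SD, n = 11) to 15.6 ± 30.4 CPM (SD, n = 24; log2 change -5.99, SE 0.90, adjusted p = 6.458e-06, edgeR). The library labelled 21 h, at 5472 CPM, raised that earlier mean. The log2 change was -5.09 without it, -4.32 without the lowest totals, -4.41 with the total as a covariate and -3.85 with spike-in scaling. Within the first series alone 2039 transcripts differed, 1171 of them higher. The balance of rises and falls depended on the scaling: 56.8% of the calls were rises with TMM, 43.6% with DESeq2 size factors, 81.4% with total counts and 98.2% with spike-ins. It also depended on the fit: with TMM, rises made up 80.2% in a fit of all windows and 65.85% with no filter on low counts.

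From 24 to 47 h to 48 to 65 h, 395 transcripts rose and 563 fell, of 5585 tested, but the later window lies mostly in the second library series. PT_v1_tr_02264 went from 60.8 ± 131 (SD, n = 24) to 3698 ± 3038 CPM (SD, n = 18; log2 change 5.91, SE 0.90, adjusted p = 4.881e-05, edgeR). Without the library labelled 47 h, at 612 CPM, the earlier mean was 36.9 CPM and the log2 change 6.56. PT_v1_tr_08291 went from 26.3 ± 46.4 (SD, n = 24) to 1215 ± 909 CPM (SD, n = 18; log2 change 5.52, SE 0.78, adjusted p = 1.376e-05, edgeR). PT_v1_tr_03178 fell from 60.4 ± 62.3 (SD, n = 24) to 3.66 ± 15.1 CPM (SD, n = 18; adjusted p = 0.002038, edgeR). PT_v1_tr_03179 fell from 60.8 ± 63.1 (SD, n = 24) to 4.94 ± 18.6 CPM (SD, n = 18; adjusted p = 0.00527, edgeR). Most of these later means came from the library labelled 48 h (64.2 and 78.9 CPM). Without it the log2 changes were -7.94 and -6.26 in place of -3.95 and -3.53. Within the first series, which holds 4 embryos of the later window, 1 of 8067 transcripts differed, with 593 at an unadjusted p under 0.05, and with the series as a covariate 5 of 5585 did. Without the libraries labelled 21, 24, 48, 62 and 72 h, 1796 transcripts differed, 597 higher and 1199 lower, and without that labelled 48 h alone 1499. All 4 named transcripts lost their call within the first series (adjusted p from 0.2405 to 0.8324, edgeR), with log2 changes of 3.89, 4.15, -1.98 and -1.55 in the order named. They were 4.32, 4.58, -6.34 and -4.06 without the library labelled 48 h. They kept their direction. These lost calls, with 4 or 3 later embryos, do not decide between age and library series, which cannot be told apart across 52 h. With the covariate PT_v1_tr_08291 kept its call (adjusted p = 0.03353, edgeR), but all 5 calls of that fit were rises, so both falls lost theirs. In that fit the library labelled 24 h, with best hour 91, was the only second-series embryo of 24 to 47 h. The first-series embryos of 48 to 65 h included that labelled 48 h, with best hour 29. The covariate fit therefore does not decide between age and library series either.

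Between 48 to 65 h and 66 to 120 h, 112 transcripts rose and 101 fell, of 5043 tested. Falls prevailed in a fit of all windows, with 224 rises and 802 falls, and with no filter on low counts, with 254 and 678. PT_v1_tr_06304 rose from 2 counts in 18 embryos to 445 ± 450 CPM (SD, n = 32; log2 change 10.42, SE 1.16, adjusted p = 3.234e-08, edgeR), a ratio of 2741 with an exact 95% counting interval of 758 to 22630. PT_v1_tr_01340 had no count in the earlier window and 70.8 ± 71.3 CPM (SD, n = 32) in the later, at least 316-fold more (adjusted p = 1.639e-06, edgeR). PT_v1_tr_07671 fell from 1105 ± 978 (SD, n = 18) to 55.5 ± 255 CPM (SD, n = 32; log2 change -4.29, SE 0.93, adjusted p = 0.00249, edgeR). PT_v1_tr_05024 fell from 626 ± 618 (SD, n = 18) to 33.3 ± 139 CPM (SD, n = 32; log2 change -4.20, SE 0.86, adjusted p = 0.001507, edgeR). The library labelled 72 h held most of these later means (1443 and 786 CPM). Without it the log2 changes were -6.62 and -6.04. The highest earlier values of both transcripts, 3665 and 2214 CPM, were in the library labelled 49 h, of the first series. All embryos of 66 to 120 h are in the second, so these log2 changes do not separate age from library series. Within the second series alone 96 transcripts differed, 61 higher and 35 lower, and 93 of these were among the 213. Without the libraries labelled 62 and 72 h the second series gave 179, 77 higher and 102 lower. Rises made up 52.6% of the calls with TMM, 70.9% with DESeq2 size factors, 65.5% with total counts and 22.5% with spike-ins.

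The first and the last window differed in 2375 of 7358 transcripts, 1488 higher and 887 lower at 66 to 120 h. PT_v1_tr_09823 had no count at 1 to 6 h and 1902 ± 797 CPM (SD, n = 32) at 66 to 120 h, at least 1494-fold more (adjusted p = 9.981e-16, edgeR). PT_v1_tr_05158 went from 0 counts to 992 ± 487 CPM (SD, n = 32; at least 748-fold; adjusted p = 4.194e-10, edgeR). In the other direction PT_v1_tr_03800, at 1160 ± 287 CPM (SD, n = 6) in the first window, had no count in any of the 32 late embryos, at least 8503-fold less (adjusted p = 1.468e-18, edgeR). PT_v1_tr_08168 went from 729 ± 152 CPM (SD, n = 6) to 0 counts in 32 embryos, at least 5176-fold less (adjusted p = 4.621e-16, edgeR). All embryos of 1 to 6 h are in the first series and all of 66 to 120 h in the second, so age and library series cannot be told apart in this comparison. Rises made up 62.7% of the calls with TMM, 53.6% with DESeq2 size factors, 83.1% with total counts, 86.0% with spike-ins, 50.5% in a fit of all windows and 42.3% with no filter on low counts.

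A single transcript dominated the early libraries. PT_v1_tr_02502, singled out after its values were seen, took 59.0% ± 7.69 (SD, n = 6) of transcript counts at 1 to 6 h, 60.2% ± 8.49 (SD, n = 6) at 7 to 12 h, 48.4% ± 11.4 (SD, n = 11) at 13 to 23 h and 29.8% ± 7.74 (SD, n = 24) at 24 to 47 h. The drop from 7 to 12 h to 13 to 23 h did not pass the test (adjusted p = 0.11, exact permutation test), but did without the libraries labelled 21, 24, 48, 62 and 72 h (46.1% ± 9.09, SD, n = 10, at 13 to 23 h, adjusted p = 0.026, exact permutation test). Of these only that labelled 21 h lies in the windows compared. Its share of 70.6% was among the reasons to doubt it, so leaving it out favours a pass, which is no independent support. The drop from 13 to 23 h to 24 to 47 h passed the test (adjusted p = 0.0001, two-sided permutation test, 5 comparisons), and the share was 27.7% ± 3.76 (SD, n = 18) and 27.2% ± 5.84 (SD, n = 32) in the last windows. All other transcripts together gave 2.87 ± 1.07 counts per spike-in count (SD, n = 11) at 13 to 23 h and 7.73 ± 1.73 (SD, n = 24) at 24 to 47 h (adjusted p = 5e-05, permutation test). They then fell from 9.08 ± 2.85 (SD, n = 18) at 48 to 65 h to 6.33 ± 2.01 (SD, n = 32) at 66 to 120 h (adjusted p = 0.0004, permutation test). Within the first series the rise gave an adjusted p of 4e-05 and within the second the fall a p of 0.0001 (permutation tests). The labels do not say whether each embryo received the same amount of spike-in.

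**Figure D2:**
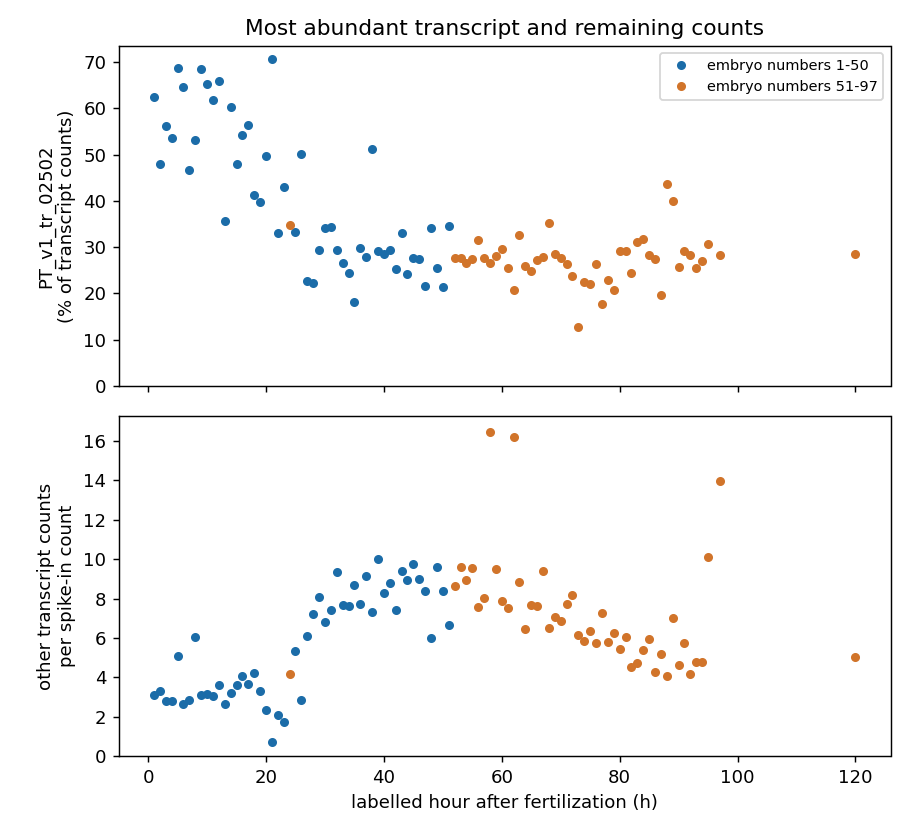
Share of transcript counts taken by PT_v1_tr_02502 in percent (upper plot, y axis) and counts of all other transcripts per spike-in count (lower plot, y axis) against the labelled hour (x axis), 1 point per embryo, blue for embryos 1 to 50 and orange for embryos 51 to 97. The share lies at 59.0% on average at 1 to 6 h and at 29.8% at 24 to 47 h, while the ratio to spike-ins goes from 2.87 at 13 to 23 h to 7.73 at 24 to 47 h.

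The number of transcripts detected was compared at an equal depth of 380093 counts, which left out 10 shallower embryos. This matched totals that include PT_v1_tr_02502, so early embryos had fewer counts for all other transcripts. It rose from 6439 ± 266 (SD, n = 5) at 1 to 6 h to 7158 ± 303 (SD, n = 5) at 7 to 12 h (adjusted p = 0.0132, two-sided exact permutation test, 5 comparisons). At 13 to 23 h it was 7399 ± 369 (SD, n = 8) and at 24 to 47 h 7897 ± 947 (SD, n = 24), steps that did not pass the permutation tests (adjusted p = 0.238 and 0.201). Without the libraries labelled 21, 24, 48, 62 and 72 h the second of these steps did pass (a rise of 664 in the mean, n = 8 and 23, adjusted p = 0.00293, permutation test). In that step this left out only the library labelled 24 h, which detected 4068 transcripts. Detection was among the grounds for picking the 5 libraries, so this pass is no independent support. With all libraries of that depth, the number detected was then 5860 ± 1576 (SD, n = 17) at 48 to 65 h and 4498 ± 640 (SD, n = 28) at 66 to 120 h (adjusted p = 0.00015 and 0.000325, permutation tests). Within the first series the mean of 48 to 51 h was 187 above that of 24 to 47 h (n = 4 and 23, p = 0.467, exact permutation test). Within the second the last step was -626 (n = 13 and 28, p = 0.013, permutation test) in place of -1362. With PT_v1_tr_02502 left out and 226155 other counts per embryo, the first rise was 593 (n = 3 and 5, adjusted p = 0.0298, exact permutation test). The next steps gave adjusted p = 0.883 (exact permutation test) and 0.663 (0.0355 without the libraries labelled 21, 24, 48, 62 and 72 h, a pass with the same limit as above), and the drops 0.0001 and 0.000125 (permutation tests). Within the first series no step passed (adjusted p = 0.0568 at the least, permutation tests). The first step held the same embryos in both (unadjusted p = 0.0179, exact permutation test), adjusted over 4 comparisons in place of 5. The step from 13 to 23 h to 24 to 47 h likewise held the embryos of the set without those 5 libraries (unadjusted p = 0.0284, permutation test). These lost calls therefore came from the adjustment and not from other embryos. Over all 87 embryos detection fell with the hour (Spearman rho -0.64, Pearson r -0.69, r -0.70 without the 2 embryos farthest from the median hour). The direction differed between the series: rho was 0.84 and r 0.84 in the first (n = 45) and rho -0.42 and r -0.35 in the second (n = 42). Without PT_v1_tr_02502 rho was 0.73 (n = 43) and -0.44 (n = 44). Permutation p was 1e-05, the smallest possible, for the pooled and first-series values, and 0.00662 for rho and 0.0262 for r in the second series.

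**Figure D3:**
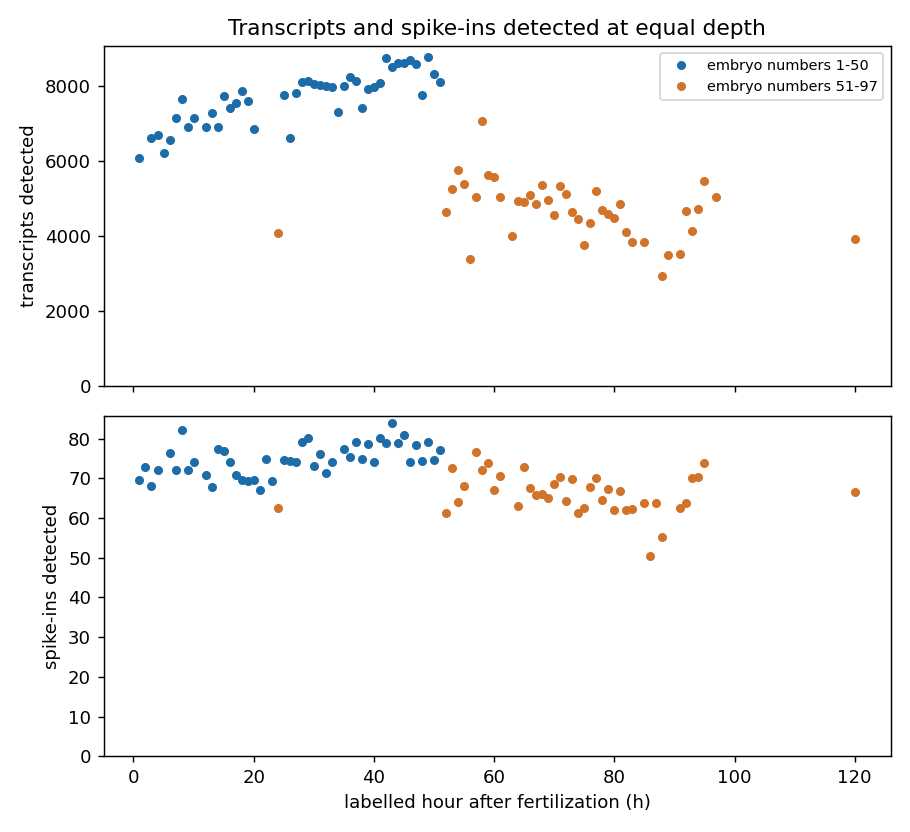
Transcripts detected at 380093 counts (upper plot, y axis) and spike-ins detected at 48975 spike-in counts (lower plot, y axis) against the labelled hour (x axis), 1 point per embryo, blue for embryos 1 to 50 and orange for embryos 51 to 97. Transcripts detected averaged 8408 at 49 to 51 h and 5214 at 52 to 54 h, and the library labelled 24 h lies with the second series.

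Embryos fell largely in the order of their labels. The first principal component held 37.2% of the variance of the 2000 most variable transcripts and followed the hour (Spearman rho 0.92, Pearson r 0.91, permutation p = 1e-05 each, the smallest possible, n = 97; r 0.92 without the 2 embryos farthest from the median hour). It did so within the first series (rho 0.97, r 0.97, permutation p = 1e-05 each, n = 50) and within the second (rho 0.72, permutation p = 1e-05, and r 0.59, permutation p = 2e-05, n = 47). When each embryo was matched to smoothed profiles of the others, the best hour lay a median of 1.0 h from the label and within 5 h for 88 of 97 embryos. An embryo's own hour was not on offer, so 1.0 h was the smallest distance possible. The best hour lay more than 12 h away for 6: the libraries labelled 24 h (best hour 91), 48 h (29), 72 h (51), 95 h (75), 97 h (82) and 120 h (84). For the library labelled 120 h this was fixed in advance, as the latest hour on offer was 97 h. Hours near the end have few neighbours, and in simulated courses single embryos were misplaced by up to 28 h.

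**Figure D4:**
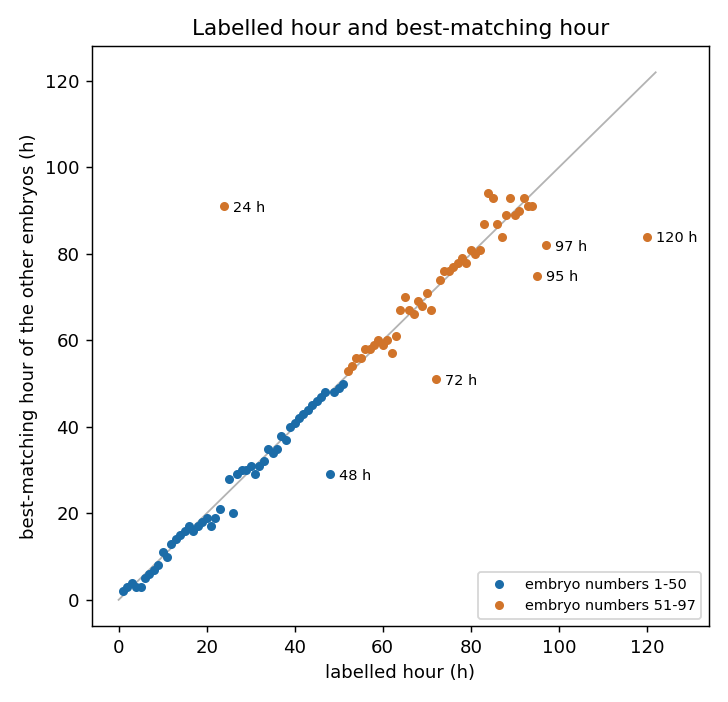
Hour at which the smoothed profile of the other embryos matched best (y axis, h) against the labelled hour (x axis, h), 1 point per embryo, blue for embryos 1 to 50 and orange for embryos 51 to 97, with the line of equal hours in grey. The 6 named libraries lie more than 12 h from their label, and 88 of 97 embryos lie within 5 h. For the library labelled 120 h the distance was fixed in advance, as the latest hour on offer was 97 h.

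The border of fastest change was not located. The distance between the 5 embryos before and the 5 after a border exceeded that of random splits most between 10 and 11 h (0.114 against 0.0568). Bootstrap draws of embryos placed the border at 19 to 85 h in their central 95%, a range that does not hold 10 h. Within the first series without the libraries labelled 21 and 48 h the range was 7.0 to 27.5 h. In each draw the distance came from the drawn embryos, but the random splits subtracted from it came from the original embryos. These ranges are therefore not a spread of the value above and do not bound the border. With 3 embryos on each side, or with Spearman correlation, the border was that between 51 and 52 h, where the library series changes.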

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

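The tests of sequencing depth, of spike-in detection and of spike-in spread in the first pattern, and those of depth and of shifted labels in the second, were chosen only after the results were seen; the others were set before.

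Fewer transcripts were detected from embryo number 51 on. Sequencing depth is argued against, since at equal depth the libraries labelled 52 to 54 h still detected 62.0% as many transcripts as those labelled 49 to 51 h. Spike-ins, which do not develop, were also detected less often in the second series at equal spike-in depth (66.3 ± 5.06, SD, n = 40, against 74.8 ± 4.02, SD, n = 47; ratio 0.886, permutation p = 1e-05, the smallest possible). Their median squared coefficient of variation was 2.79 times as large there, higher for 41 of 42 spike-ins, which argues against development as the whole cause. A lower recovery of molecules in the second series is therefore a candidate explanation, and a developmental part of the drop stays open, because age and series cannot be separated across 52 h.

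The libraries labelled 24, 48 and 72 h matched other hours best (91, 29 and 51). Low depth is argued against by the lowest of their totals, 632077, which is above the 10th percentile of 380093. Likeness within a library series alone was tested on the library labelled 24 h, which among first-series profiles matched the last available hour, 51 (r 0.23). The second-series libraries labelled 62, 95, 97 and 120 h matched that hour too, at r from 0.19 to 0.42. No other second-series library has an early label, so this match cannot tell age from likeness within a series. The library labelled 48 h, itself of the first series, matched 28 h among first-series profiles (r 0.89). A passing on of labels by 1 day among whole-day libraries would put them at 96, 24 and 48 h, and the largest distance from these was 5.0 h, while the library labelled 120 h lay 12 h from 96 h. This explanation came from the same best hours, so they cannot decide on it. The embryo numbers are separate from these hours. The library labelled 24 h is number 95, next after number 94, labelled 95 h, and no library is labelled 96 h. Those labelled 48 and 72 h, numbers 47 and 71, stand in the order of their labels, so the numbers do not bear out a shift for them. The explanation stays open, and no biological explanation was tested.

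The library labelled 21 h was first thought to resemble the earliest hours, from its 3765 detected transcripts and a 70.6% share of PT_v1_tr_02502. Depth alone is argued against: of 5 neighbours 3 were thinned to its total and 2 held fewer counts already, and in that check their best hours lay at most -2.0 h from their labels. In the main match the library labelled 22 h, 1 of the 2 shallower ones, lay -3 h from its label. Whether the embryo of the library labelled 21 h stopped developing early stays open, since its best hour was 17 (r 0.51, against 0.47 for the best of 1 to 6 h). Leaving out PT_v1_tr_02502 tested nothing, as that transcript ranked 9339 by variance and the match used 2000. Transcripts highest at 13 to 23 h had a median log2 difference of 0.00 from 1 to 6 h in it and 2.54 in the libraries labelled 20 and 22 h, as an early stop would give, but 47.8% of them had no count in it. A library of few molecules could give such values too and was not tested.

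Chance division of the embryos is argued against for each of the 6 window comparisons, where only the real division, 1 of 100, gave as many transcripts. With 100 divisions chance cannot be excluded. Other borders along the hours were not tried, so the borders chosen were not tested by this. The real and the highest other counts were 131 and 24 for 7 to 12 h against 1 to 6 h, 562 and 235 for 13 to 23 h against 7 to 12 h, and 1775 and 65 for 24 to 47 h against 13 to 23 h. They were 958 and 1 for 48 to 65 h against 24 to 47 h, 213 and 0 for 66 to 120 h against 48 to 65 h, and 2375 and 24 for 66 to 120 h against 1 to 6 h. Which embryos made up the division with 235 was not examined. These divisions do not separate age from library series, which part 14 of the 18 embryos of 48 to 65 h from 23 of the 24 of 24 to 47 h, and all embryos of 66 to 120 h from those of 1 to 6 h.

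In the windows of 6 embryos, 2 of 24 sets of values held an embryo far from the others. Chance gives about 1 in 20 for values that vary continuously, and 1 of the 2 sets is not of that kind, so the number is no sign of more than chance. The library labelled 5 h had 16.2 transcript counts per spike-in count, against 5.99 to 8.24 in the other libraries of 1 to 6 h. PT_v1_tr_06540 stood at 2.83 CPM, scaled over all 97 embryos, in the library labelled 1 h and at 0 in the other 5. That level was 1 count, so the gap was forced and shows nothing about that embryo. Reads that aligned to neither transcripts nor spike-ins had a median share of 55.05% of all counts per embryo and were not analysed here.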

How the results depend on the processing

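Scalings other than DESeq2 size factors, fits by library series and fits without the libraries labelled 21, 24, 48, 62 and 72 h, together or singly, were chosen after the data were seen. Counts of differing transcripts moved by over 1.5 times as follows, and except where fewer embryos entered the fit the cause was not tested. For 7 to 12 h against 1 to 6 h (131) the DESeq2 Wald test gave 215, no filter 308, leaving out the lowest totals 66, leaving out border hours 227, and leaving out single embryos 71 to 216. For 13 to 23 h against 7 to 12 h (562) the Wald test gave 931, a fit of all windows 126 (118 rises), the library total as covariate 363 and spike-in scaling 270. Leaving out single embryos gave 348 to 631 there, of which only the lower end lies past 1.5 times. For 24 to 47 h against 13 to 23 h (1775) no filter gave 2867, the total as covariate 1091 and spike-in scaling 3592. For 48 to 65 h against 24 to 47 h (958) the Wald test gave 1609, no filter 1902, leaving out the 5 doubted libraries 1796, leaving out that labelled 48 h alone 1499, the first series 1, the series as covariate 5, and the first series without the doubted libraries 5. For 66 to 120 h against 48 to 65 h (213) the Wald test gave 453, no filter 932, a fit of all windows 1026, the second series 96 and the series as covariate 95. For 66 to 120 h against 1 to 6 h (2375) a fit of all windows gave 4136. Leaving out single embryos gave 1789 to 1859 there, which is within 1.5 times. The time course (6353) gave 4032 with the series as covariate and 2339 in the second series.

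Scaling moved the median log2 change of all transcripts. For 24 to 47 h against 13 to 23 h it was 0.09 with TMM, -0.09 with DESeq2 size factors, 0.46 with total counts and 1.38 with spike-ins; for 13 to 23 h against 7 to 12 h it was 0.01 with TMM, 0.13 with total counts and -0.54 with spike-ins. For 66 to 120 h against 1 to 6 h it was 0.03, -0.25, 0.87 and 0.98 in the first order, for 66 to 120 h against 48 to 65 h -0.12, 0.16, 0.09 and -0.37, and for 7 to 12 h against 1 to 6 h -0.01 with TMM and 0.14 with spike-ins.

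Transcripts detected fell with the hour in the pooled embryos and rose in the first series (rho 0.84, 0.86 without the doubted libraries, and 0.73 with PT_v1_tr_02502 left out). The border of fastest change moved from 10 h to 51 h with 3 embryos on each side and with Spearman correlation, and to 71 h in the second series without the doubted libraries. By median CPM, 743 transcripts peaked at 66 to 120 h; with a mean of at least 20 CPM the 6 windows held 465, 414, 422, 881, 344 and 576, as fewer transcripts entered. The order along the first component and the median distance of the best hour kept their direction and side of the threshold in all alternatives run. That median distance stood at 1.0 h throughout, the smallest possible. Of the values of named transcripts that reached the test, 351 kept direction and call and 30 lost the call, with none reversed. Fits in which a named transcript did not reach the test, as with PT_v1_tr_03245, are in neither number. No paired analysis was possible because replicate numbers only follow the hour.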

Other observations

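With TMM scaling, transcripts highest at 1 to 6 h were by definition lower in all later windows, so only the size and course of the fall are described here. The 1161 transcripts highest at 1 to 6 h were followed through the first library series without the doubted libraries, a choice made after the data were seen. Their median level relative to 1 to 6 h was 0.749 at 7 to 12 h (n = 6), 0.490 at 13 to 17 h (n = 5), 0.347 at 18 to 23 h (n = 5), 0.322 at 25 to 30 h (n = 6) and 0.259 at 43 to 51 h (n = 8). The share below a relative level of 0.5 was 11.5% at 7 to 12 h, 51.9% at 13 to 17 h, 71.3% at 18 to 23 h, 67.8% at 25 to 30 h and 79.2% at 43 to 51 h; no test of the shape was run. Relative to spike-in counts the median level was 0.812 at 7 to 12 h, 0.467 at 13 to 17 h, 0.266 at 18 to 23 h, 0.451 at 25 to 30 h, 0.603 at 31 to 36 h and 0.493 at 43 to 51 h, so the course after 24 h depended on the scaling. Because these transcripts were picked for being highest in the first window with TMM scaling, the direction of that decline follows from the choice itself, and part of its size may too.

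Counts of PT_v1_tr_02502 per spike-in count were 5.66 ± 1.74 (SD, n = 6) at 7 to 12 h and 2.80 ± 1.46 (SD, n = 11) at 13 to 23 h (adjusted p = 0.0105, exact permutation test), and 3.27 ± 1.20 (SD, n = 24) at 24 to 47 h. Its later loss of share, from 48.4% to 29.8%, thus came with more counts of other transcripts per spike-in, and its own ratio to the spike-ins did not pass the test at that step (adjusted p = 0.55, permutation test).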
